A study of Mus musculus with 18 samples.

How the data were processed

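The series holds 18 Affymetrix arrays of biotin-labelled total RNA from mouse bone marrow cells. Per the labels' protocols, marrow was taken 4 days after an injection of 5-fluorouracil, transduced by retrovirus, and kept for 48 hours before sorting and for another 24 hours before RNA was extracted with the RNeasy micro kit. Labelling followed the whole transcript sense target assay, and the culture medium held IL3, IL6 and SCF, both per the labels' protocols. The labels' transduction field puts the arrays in 6 groups of 3: empty vector (MiG), AML1-ETO (AE), Meis2, AE_Meis2, Meis1 and AE_Meis1. The labels do not say whether the 3 arrays of a group come from separate animals or cultures. Title codes run in 3 sets of 6 consecutive codes, each with 1 array of every group, and the labels give them no meaning. No array was left out of the main results.

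The deposited values are on a log2 scale and were made with Affymetrix Power Tools, version not given, per the submitters' processing notes. Background correction, normalization, summarization and the log base are not given in the sources used here. The log base was checked on the table: of the 2534 values below 0, 100% were log2 of a whole multiple of 1e-05, within 0.01 of 1 such multiple, against 2.09% if read as natural logs. Array medians ran from 7.60 to 7.83 and upper quartiles from 9.04 to 9.53, and whether values were scaled to a common target or centred in another way stays unknown. The table has no background or detection column, so no value could be called present or absent. No 2 arrays were identical (0 identical pairs).

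The table has 35556 probe sets. The platform's gene table listed 21789 with 1 gene symbol and 1621 with several, and did not list the other 12146, which are unnamed here and may still measure a gene. Symbols were compared with the reference gene table through gene identifiers, which matched for 21698 probe sets, and 0 were updated. Probe sets with several symbols were not named. Where a gene had several probe sets, the one with the highest mean over the 18 arrays stood for it, which gave 19938 genes.

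Genes were tested in R 4.3.3 with limma 3.58.1 (tables handled with data.table, version 1.17.8). A mean per group was fitted to all 18 arrays with lmFit, which left 12 residual degrees of freedom, and eBayes moderated the variances. The 11 comparisons were AE, Meis2, AE_Meis2, Meis1 and AE_Meis1 against MiG, AE_Meis2 against AE and against Meis2, AE_Meis1 against AE, Meis2 against Meis1, AE_Meis2 against AE_Meis1, and the interaction of AML1-ETO with MEIS2, that is the MEIS2 difference with AML1-ETO minus the MEIS2 difference without it. P-values were two-sided and adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. Errors of differences are standard errors from the fit, and errors of group means are SD over 3 arrays. An exact test of 3 arrays against 3 cannot give a two-sided p under 0.1, so p-values rest on the variance shared across groups and genes. Differences within a title-code set are between 1 array and 1 array and have no test.

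The genes to name were set by rule: the construct genes and Yes1 always, then up to 10 genes per direction among those that passed and whose groups did not overlap. Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values that did not pass. Up to 4 members with the smallest p were named from each list described, and up to 6 lists were described per comparison. Predicted genes and names of the Gm, Rik, Mir, Snord, Snora, olfactory, vomeronasal and antigen receptor segment kinds were counted but not named. These rules, the comparisons, the lists and the alternatives not marked otherwise in the closing section were chosen before the data were examined.

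Of 26 gene lists, 25 were tested and the list of construct genes (Runx1, Runx1t1, Meis1, Meis2) was reported gene by gene. The lists covered Src family kinases, myeloid regulators and receptors, neutrophil granules, monocytes and macrophages, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes, stem and progenitor cells, the HOX and PBX program, B cells, T and NK cells, dendritic cells and MHC class II, and stromal and endothelial cells. The others were mitotic cell cycle, DNA replication, p53 targets, DNA repair, interferon response, cytokines and chemokines, cholesterol synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, Wnt and plakoglobin, and reported AML1-ETO targets. A list needed at least 3 measured members. Each was tested with camera at a preset correlation of 0.01, with camera at the correlation estimated from the residuals, and with fry, adjusted over the lists of a comparison (275 list results in all). Members were also counted at an adjusted p under 0.05 over all genes and over the list alone. List sizes of change are medians over measured members.

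Agreement of comparisons was described by Pearson and Spearman correlation across genes, with 100 simulations of unchanged groups for the 2 comparisons that share the MiG arrays, with the residual spread of all 18 arrays and, chosen after the data were seen, with the spread of the 9 arrays of the 3 groups once title-code set means were removed. Splits of the compared arrays were refitted, the real one included: all 10 for 6 arrays, and 100 for the 12 arrays of the interaction, the others drawn with a fixed seed.

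The alternatives were: leaving out the 40% of genes with the lowest mean, quantile normalization, testing every probe set, fitting the compared groups alone, eBayes with trend and robust, array weights, the title-code set as a block, the estimated correlation in camera, and leaving out each array of the compared groups. Further ones were the gene-by-gene method of array weights, leaving out the second AE_Meis1 and AE_Meis2 arrays, leaving out the second title-code set (6 residual degrees of freedom), and raising values under 4 to 4.

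The code was tested on simulated data with 50 changed genes at each size, drawn with the means and spread of these arrays. For AE against MiG it recovered 2% of genes changed by 1 on the log2 scale, 62% at 2, 94% at 4 and 100% at 6. For AE_Meis2 against AE it recovered 6%, 58%, 98% and 100%. Of the 19738 unchanged genes, 0.0253% passed in each of these comparisons. With the 20 neutrophil granule genes lowered by 1 in Meis1 against MiG, that list passed in camera at the preset correlation and 0% of the other lists did. The simulated noise was independent between genes and between arrays, so it holds no title-code sets and no correlation within lists.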

Results

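The 18 arrays cover 6 groups of 3: mouse bone marrow cells with the empty GFP vector (MiG), with AML1-ETO (AE), with MEIS2, with MEIS1, and with AML1-ETO joined by MEIS2 (AE_Meis2) or MEIS1 (AE_Meis1). Runx1t1, which encodes the ETO part of the fusion, had a mean log2 value of 12.6 ± 0.14 (SD, n = 3) in AE, 12.5 ± 0.12 in AE_Meis2 and 12.6 ± 0.11 in AE_Meis1. It stood at 6.43 ± 2.10 in MiG, 6.88 ± 1.86 in Meis2 and 6.90 ± 2.48 in Meis1. Meis2, a homeodomain partner of HOX proteins, measured 13 ± 0.06 in Meis2 and 12.7 ± 0.39 in AE_Meis2, against 5.04 ± 2.63 in MiG, 5.28 ± 2.19 in AE, 5.50 ± 1.45 in Meis1 and 6.54 ± 2.43 in AE_Meis1. Its relative Meis1 measured 12.8 ± 0.10 in Meis1 and 12.5 ± 0.48 in AE_Meis1, against 8.35 ± 0.48 in MiG, 8.62 ± 0.59 in AE, 8.91 ± 1.02 in Meis2 and 8.15 ± 0.94 in AE_Meis2. Runx1, the gene of the AML1 part, had group means from 11.2 in AE_Meis2 to 11.9 in Meis1. Differences were tested with limma, and the labels do not say whether replicates are separate cultures or animals, so each p-value measures only the spread between these samples.

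**Figure D1:**
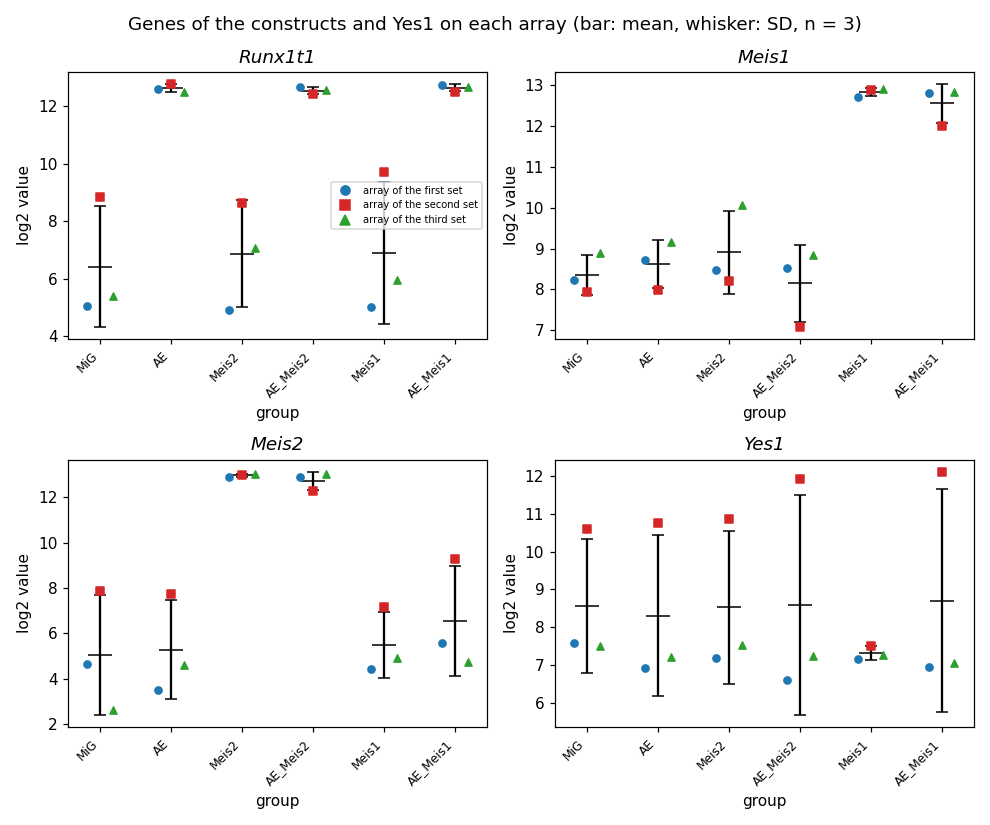
Deposited log2 value of Runx1t1, Meis1, Meis2 and Yes1 on each array, by group; points are arrays, marked by the set of title codes, bars are means and whiskers SD (n = 3). Groups given Runx1t1 or Meis2 sat near 12.5 to 13, and the second-set arrays of the other groups lay above the other arrays of their group for Runx1t1 and Meis2.

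The 6 arrays of the second title-code set stood apart. Ebf1, a B-lineage transcription factor, had a mean of 10.8 on those 6 arrays (9.98 to 11.6) and 2.90 on the other 12 (-0.17 to 3.81). Lef1 averaged 14.7 against 8.13, Pax5 10.7 against 6.54 and Mest 12.7 against 3.84, and the empty vector array of that set was among the high ones, with 10.6 for Ebf1 and 14.5 for Lef1. The median Spearman correlation with the other arrays was 0.676 for the second AE_Meis1 array and 0.522 for the second AE_Meis2 array, and at least 0.910 for each of the remaining 16. Values without the second set are given for the construct genes, Mmp2, some other genes and some lists. Of 221 differences of single genes other than Yes1, leaving out that set moved 53 by over 1.5 times. Leaving out 1 array moved 91 so, 34 of them with the second AE_Meis2, 22 with the first AE_Meis1 and 16 with the third Meis1 array.

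**Figure D2:**
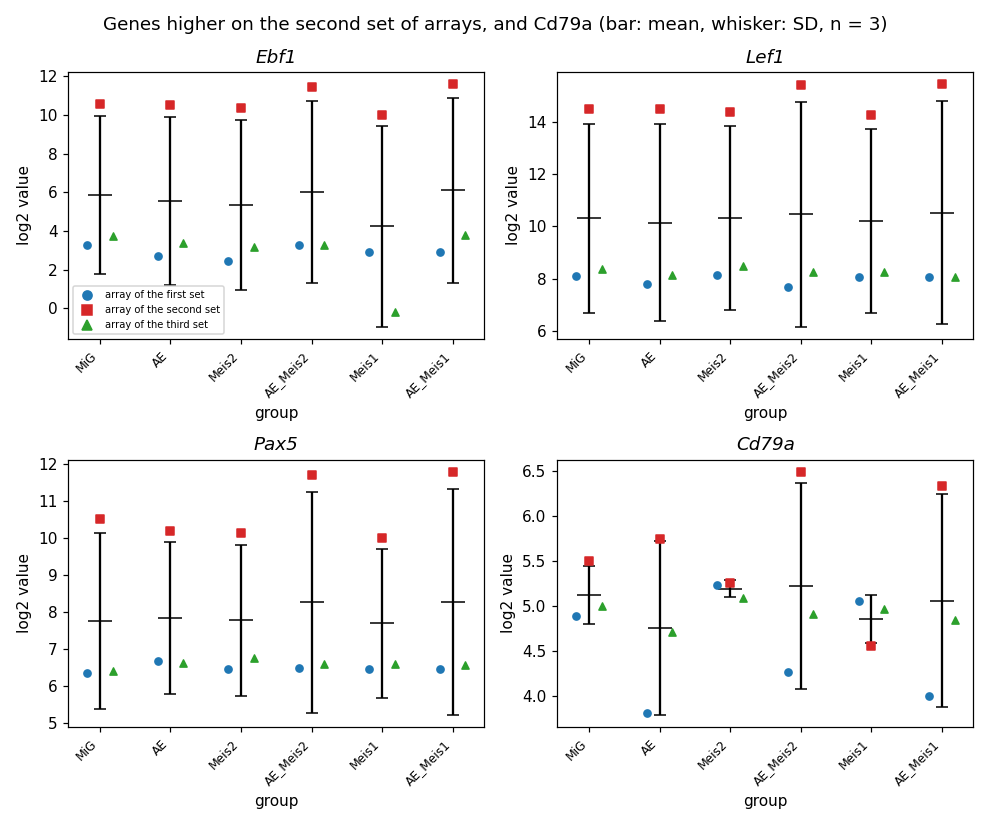
Deposited log2 value of Ebf1, Lef1, Pax5 and Cd79a on each array, by group; points are arrays, marked by the set of title codes, bars are means and whiskers SD (n = 3). The 6 second-set arrays held 9.98 or more for Ebf1, against at most 3.81 elsewhere, while Cd79a averaged 5.65 on them and 4.73 elsewhere.

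Yes1, a Src family kinase, had group means of 8.57 ± 1.75 in MiG, 8.31 ± 2.13 in AE, 8.53 ± 2.01 in Meis2, 8.59 ± 2.89 in AE_Meis2, 7.32 ± 0.18 in Meis1 and 8.71 ± 2.94 in AE_Meis1. The difference of AE_Meis2 from AE was 0.28 ± 1.47 (SE, n = 3; adjusted p = 0.923). It was -0.33, 1.14 and 0.03 in the first, the second and the third set and -0.15 without the second set. Yes1 lay between 7.52 and 12.1 on the second-set arrays and between 6.61 and 7.59 on the others. Against MiG, the Yes1 difference was -0.26 for AE, -0.033 for Meis2, 0.025 for AE_Meis2, -1.24 for Meis1 (-0.23 without the second MiG array, -0.33 without the second set) and 0.14 for AE_Meis1. It was 0.058 for AE_Meis2 against Meis2, 0.31 in the interaction, 0.40 for AE_Meis1 against AE, 1.21 for Meis2 against Meis1 (0.054 without the second Meis2 array, 0.15 without the second set) and -0.12 for AE_Meis2 against AE_Meis1. No Yes1 difference passed, with adjusted p from 0.923 to 1 over the 11 comparisons. The list of 6 measured Src family kinases passed in no comparison; its smallest adjusted p was 0.258, in Meis1 against MiG.

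With AML1-ETO alone, Runx1t1 was 6.18 ± 1.05 (SE, n = 3) above the empty vector. Its adjusted p was 0.256, and 0.0132 without the second set. Csgalnact1, an enzyme of chondroitin sulfate synthesis, was 1.89 ± 0.71 higher, Lcn4 1.26 ± 0.48, Dcbld1 0.99 ± 0.39 and Chst13 0.96 ± 0.38. The lowest p-values among lower genes belonged to Svs3b at -0.75 ± 0.36, Slc37a2 at -0.70 ± 0.38, Zfp616 at -0.87 ± 0.49 (-0.37 once values under 4 were raised to 4, -0.40 without the first AE array), Bche at -0.61 ± 0.35 and Efcab3 at -0.65 ± 0.37 (adjusted p = 1 for each gene but Runx1t1). No gene passed in limma, with 17 at an unadjusted p under 0.05, 1 (Runx1t1) without the second set or with the set as a block, and 123 with gene-by-gene array weights. For 449 genes the groups did not overlap, 2.25%, where chance gives 10% for independent arrays. Arrays of a title-code set shared deviations, so that share is given for scale and is no chance level fitted to these arrays.

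Monocyte and macrophage genes fell with AML1-ETO, with a median of -0.41 over 20 measured members and all 20 below 0, among them Cd68 at -0.41 (adjusted p = 0.732 with an estimated correlation). Their medians within the sets were -0.37, -0.45 and -0.24. Mast cell and basophil genes rose, with a median of 0.35 and 13 of 15 members above 0, including the basophil protease Prss34 at 1.57 ± 0.64 (1.04 without the first MiG array), and Hdc, which makes histamine, at 0.65 (adjusted p = 0.737 with an estimated correlation). Stem and progenitor genes rose by a median of 0.23, with 14 of 20 members above 0 and Mycn at 0.87 and Hlf at 0.84 (adjusted p = 0.732 so estimated). Megakaryocyte genes rose by a median of 0.36, with Gp5 at 0.71 (adjusted p = 0.737 so estimated). Hypoxia and glycolysis genes rose by a median of 0.069, which was -0.007 without the second set (adjusted p = 0.737 so estimated). No member of these 5 lists passed, over all genes or adjusted over the list alone, and 1 list passed without the second set. Without the first MiG array the adjusted p was 0.273 for the mast cell list, 0.277 for the megakaryocyte list and 0.167 for the stem list. Without the second AE array it was 0.0686 for the monocyte list, 0.141 for the megakaryocyte list, 0.104 for the stem list and 0.566 for the hypoxia list, and without the third AE array 0.0749 for the mast cell list. The hypoxia list was also lost without the first AE array (0.051), the second MiG array (0.0509) and the third MiG array (0.085).

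With MEIS2 alone, Meis2 was 7.92 ± 1.23 above the empty vector (adjusted p = 0.0892; 0.0026 without the second set). Mmp2, a gelatinase of the extracellular matrix, was 2.2 ± 0.43 higher (adjusted p = 0.773; 0.087 without the second set) and was 2.97, 1.97 and 1.66 higher within the 3 sets. Rhobtb3 was 1.37 ± 0.35, the copper carrier Cp 1.39 ± 0.42 and the secreted Stc2 1.22 ± 0.37 higher. Camp, a granule antimicrobial peptide, stood at -1.88 ± 0.57, and within the sets at -1.71, -1.22 and -2.72. Ankrd22 at -1.66 ± 0.55, Itgb2l at -1.53 ± 0.52, Ly6g2 at -0.89 ± 0.31 and the mannose receptor Mrc1 at -1.48 ± 0.52 were the other genes with the lowest p-values among lower ones (adjusted p = 1). No gene passed in limma, with 62 at an unadjusted p under 0.05, 1 (Meis2) with the set as a block, 41 with gene-by-gene array weights and 243 with default array weights. The groups did not overlap for 876 genes, 4.39%. Meis2 and Mmp2 passed without the second AE_Meis1 and AE_Meis2 arrays.

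Neutrophil granule genes fell with MEIS2, by a median of 0.74 with 17 of 20 members below 0 (adjusted p = 1.95e-15; 0.19 with an estimated correlation). Ltf stood at -2.37 ± 0.91, Cd177 at -1.67 ± 0.62 and Itgb2l at -1.53. The list's medians were -0.57, -0.47 and -0.90 within the sets and -0.79 without the second set. There 4 members passed adjusted over the list alone, against 0 with all arrays. Donor sex may contribute: by Xist and Kdm5d, both arrays were male in the first set, and Meis2 male but MiG female in the third. Monocyte and macrophage genes fell by a median of 0.41, with Mrc1 at -1.48 (adjusted p = 0.19 with an estimated correlation), and by 0.62 without the first Meis2 array. Hypoxia and glycolysis genes rose by a median of 0.26, with 17 of 19 above 0 and Bnip3 at 0.97 and Egln3 at 0.65 (adjusted p = 0.19 so estimated); the median was 0.15 without the second set and -0.014 in the third set. Eosinophil genes fell, with all 8 members below 0, a median of -0.32 and Epx at -1.10 (-0.53 without the third MiG array) (adjusted p = 0.0521 so estimated), and a median of -0.17 without the first Meis2 array. The cytokine and chemokine list passed as higher with a mean of 0.34, while its median was -0.023 and only 9 of 21 members lay above 0 (adjusted p = 0.205 so estimated). Il1a was 3.0 ± 1.36, Cxcl2 1.24 ± 0.61 (0.77 without the first MiG array, 2.01 without the second) and Il1b 1.21 ± 0.54 higher. The list's adjusted p was 0.685 without the first MiG array and 0.0751 without the third Meis2 array. Unfolded protein and amino acid stress genes rose by a median of 0.12, with Vldlr at 1.18 (adjusted p = 0.783 so estimated; 0.177, 0.169 and 0.0966 without the first Meis2, the second Meis2 and the first MiG array with the preset one). DNA replication and DNA repair genes also passed as higher, with medians of 0.12 and 0.17 (adjusted p = 0.783 so estimated for both).

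With AML1-ETO and MEIS2 together, Meis2 was 7.69 ± 1.23 and Runx1t1 6.11 ± 1.05 above the empty vector (adjusted p = 0.13 and 0.148; 0.0026 and 0.00609 without the second set). Mmp2 was 1.93 ± 0.43 higher, at 3.02, 0.40 and 2.38 within the sets, with an adjusted p of 1 that was 0.0252 without the second set. Dcbld1 was 1.55 ± 0.39 and Rhobtb3 1.36 ± 0.35 higher. The kallikrein Klk1b22 was at -1.63 ± 0.39, with -1.72, -1.39 and -1.76 within the sets. Tlr13, a sensor of bacterial RNA, was at -2.13 ± 0.59, the chemokine receptor Ccr2 at -1.81 ± 0.51, Ifitm6 at -2.50 ± 0.71 and Lsp1 at -1.42 ± 0.44 (adjusted p = 1). Tlr13, Ccr2 and Lsp1 were at -1.38, -1.09 and -0.94 without the second AE_Meis2 array. No gene passed in limma, with 128 at an unadjusted p under 0.05, 2 with the set as a block, 675 with gene-by-gene weights and 6026 with default weights, which gave most of the weight to 1 array. Some 336 genes had groups that did not overlap, 1.69%. Without the second AE_Meis1 and AE_Meis2 arrays, 3 genes passed: Mmp2, Dcbld1 and BC018473, the last named after its values were seen and 1.28 higher with all arrays.

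Monocyte and macrophage genes fell in AE_Meis2 by a median of 1.03 from the empty vector, with 19 of 20 below 0, Ctss at -1.98 and Cd68 at -1.08 (-1.09 and -0.57 without the second AE_Meis2 array; adjusted p = 8.26e-17; 0.123 with an estimated correlation). The medians were -0.29, -2.22 and -0.81 within the sets, and 1 member passed adjusted over the list alone, against 0 over all genes. Neutrophil granule genes fell by a median of 0.73, with Ltf at -2.49 (adjusted p = 0.681 with an estimated correlation), and their adjusted p was 0.293 without the second AE_Meis2 array. Cholesterol synthesis genes fell, all 17 below 0 with a median of -0.50 (adjusted p = 0.681 so estimated), but the median was -0.069 without the second AE_Meis2 array. Mitotic cell cycle genes fell by 0.34, myeloid regulators and receptors by 0.41, with Csf1r at -1.06 (-0.13 without the second AE_Meis2 array, -1.67 without the first), and unfolded protein genes by 0.29 (adjusted p = 0.793 so estimated for each). Without the second AE_Meis2 array these 3 medians were 0.16, 0.15 and 0.07. DNA replication genes (median -0.29), DNA repair genes (-0.41) and mast cell genes (-0.71) also passed as lower and stromal and endothelial genes (0.21) as higher, with adjusted p from 0.793 to 0.796 so estimated, and 3 of the 25 lists passed without the second set.

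Adding MEIS2 to AML1-ETO left Meis2 7.46 ± 1.23 above AE (adjusted p = 0.192; 0.00382 without the second set) and Mmp2 2.10 ± 0.43 above it (0.881; 0.0399 without the second set). Mmp2 was 2.77, 0.93 and 2.59 higher within the sets. Rhobtb3 was 1.10 ± 0.35, Cp 1.22 ± 0.42 and Rab34 1.02 ± 0.37 higher. Klk1b22 was at -1.88 ± 0.39, E-cadherin (Cdh1) at -1.79 ± 0.46, Prss34 at -2.10 ± 0.64, the steroid enzyme Akr1c18 at -2.66 ± 0.82 (-1.74 without the second AE_Meis2 array) and Fam20a at -1.69 ± 0.54 (adjusted p = 0.881). Prss34 was -1.71, -3.44 and -1.14 within the sets. No gene passed in limma, with 89 at an unadjusted p under 0.05, 2 (Klk1b22 and Meis2) with the set as a block, 9 with default and 259 with gene-by-gene weights. Without the second AE_Meis1 and AE_Meis2 arrays 2 genes passed, Mmp2 and BC018473, the latter 1.21 higher with all arrays. The groups did not overlap for 275 genes, 1.38%.

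Mast cell and basophil genes fell on adding MEIS2 to AML1-ETO, with a median of -0.88, 14 of 15 below 0, Mcpt8 at -1.57 ± 0.60 and Gata2 at -1.39 ± 0.72 (adjusted p = 0.51 with an estimated correlation, as for each list of this comparison that passed). The medians were -0.17, -2.12 and -0.48 within the sets, and without the second AE_Meis2 array the median was -0.29 (adjusted p = 0.137), with Mcpt8 at -0.77 and Gata2 at -0.66. Neutrophil granule genes fell by 0.83, with Ltf at -2.37, and were at -0.36 without that array (adjusted p = 0.0864). Monocyte genes fell by 0.64, and were at -0.078 without it. Cholesterol synthesis genes (-0.48), mitotic genes (-0.36) and DNA replication genes (-0.33) fell as well, and were at -0.049, 0.12 and 0.16 without it. The 8 further lists that passed were myeloid regulators (-0.46), megakaryocyte (-0.66), DNA repair (-0.51), unfolded protein (-0.26), hypoxia (-0.32) and reported AML1-ETO target genes (-0.50) as lower, and B cell (0.22) and stromal genes (0.30) as higher. No member of the 14 lists passed adjusted over the list alone, and 1 list passed without the second set, the neutrophil granule genes at -0.41.

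Adding AML1-ETO to MEIS2 left Runx1t1 5.66 ± 1.05 above Meis2 (adjusted p = 0.734; 0.0308 without the second set). Tdpoz3 at 0.87 ± 0.33, Nlrp4e at 1.11 ± 0.50 (0.39 without the third Meis2 array), Ptprb at 0.74 ± 0.40 and A26c3 at 1.13 ± 0.61 followed by p. Nlrp4e had means of 3.96 and 2.85, and its difference was 0.155 once values under 4 were raised to 4. Lower genes were led by Aldh1l2, a mitochondrial folate enzyme, at -1.06 ± 0.37, Cd72 at -1.41 ± 0.50, Nos2 at -1.53 ± 0.56, Saa4 at -0.94 ± 0.35 and Ndrg1 at -1.46 ± 0.56 (adjusted p = 0.883). Ptprb, A26c3, Cd72 and Ndrg1 were at 0.28, 0.60, -0.86 and -0.88 without the second AE_Meis2 array, and Nos2 at -2.30 without the third Meis2 array. No gene passed in limma, with 30 at an unadjusted p under 0.05, 1 (Runx1t1) with the set as a block, 2 (Runx1t1 and BC018473) with gene-by-gene weights and 1976 with default weights. BC018473 was 0.46 higher. Some 149 genes had groups that did not overlap, 0.747%.

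Hypoxia and glycolysis genes fell on adding AML1-ETO to MEIS2, with a median of -0.48, 17 of 19 below 0, Bnip3 at -1.21 ± 0.48 and Ddit4 at -0.89 ± 0.41 (adjusted p = 8.04e-07; 0.682 with an estimated correlation). The medians were -0.33, -1.65 and 0.0041 within the sets and -0.17 without the second AE_Meis2 array. Bnip3 was at -0.68 and Ddit4 at -0.44 without the second set. Unfolded protein genes fell by 0.42, and were at -0.022 without that array (adjusted p = 0.758 with an estimated correlation). Cholesterol (-0.46), mitotic (-0.41), DNA replication (-0.43) and DNA repair genes (-0.53) fell (adjusted p = 0.758 so estimated), and without that array were at 0.011, 0.12, 0.14 and 0.21; the cholesterol list had an adjusted p of 0.0592 without the second Meis2 array. Monocyte (-0.62) and mast cell genes (-0.55) also passed as lower, and eosinophil (0.24) and stromal genes (0.24) as higher, with adjusted p from 0.682 to 0.758 so estimated. Without the second set 6 lists passed, the hypoxia genes among them at -0.14.

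The interaction asks whether MEIS2 moved genes by a different amount with AML1-ETO than without it. Bnip3, a hypoxia-induced mitophagy receptor, departed from the sum of the single effects by -1.71 ± 0.68 (SE), Plod2 by -2.12 ± 0.86, Prss34 by -2.20 ± 0.91, Ciart by -2.09 ± 0.83 and Prelid2 by -2.18 ± 0.90 (-1.22 without the second AE_Meis2 array). Bche at 1.17 ± 0.49, Tex24 at 1.26 ± 0.56, Enam at 1.27 ± 0.58, Acsbg3 at 1.0 ± 0.50 and Tdpoz3 at 0.88 ± 0.47 departed upward (adjusted p = 0.873 for each named gene). Without the second set Bche was at 0.56, Tex24 at 0.11, Enam at 0.31, Acsbg3 at 0.41 and Tdpoz3 at 0.71. Bnip3 was then at -0.98, Plod2 at -1.24, Prss34 at -1.64, Ciart at -0.74 and Prelid2 at -1.04. No gene passed in limma, with 15 at an unadjusted p under 0.05 and 0 with the set as a block or with either kind of array weights. The median of all genes was -0.11 and moved to 0.0058 with quantile normalization. It moved likewise from -0.09 to 0.057 in AE_Meis2 against MiG, from -0.097 to 0.021 against AE and from -0.092 to 0.038 against Meis2.

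Hypoxia and glycolysis genes passed as lower in the interaction, with a median of -0.64, 17 of 19 below 0, and Egln3 at -1.17 (adjusted p = 1.48e-06; 0.752 with an estimated correlation, as for each of the 8 lists). Their medians were -0.53, -1.95 and 0.020 within the sets and -0.30 without the second AE_Meis2 array. Egln3 was at -0.41 without the second set. Mast cell genes passed with a median of -0.84, all 15 below 0, and their median went from -1.68 without the third AE_Meis2 array to -0.35 without the second (-0.37, adjusted p = 0.35, without the third Meis2 array). DNA replication (-0.44), mitotic (-0.43), DNA repair (-0.67) and unfolded protein genes (-0.36, Vldlr at -2.06) passed as lower, and without the second AE_Meis2 array stood at 0.069, 0.089, 0.11 and -0.031. Megakaryocyte genes (-0.85) and cholesterol genes (-0.41) passed too, and the cholesterol median was 0.22 without the second set, where 5 lists passed.

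With MEIS1 alone, Meis1 rose by 4.47 ± 0.52 (adjusted p = 0.00139), and by 4.48, 4.92 and 4.02 within the sets; it was the 1 gene that passed, with 112 at an unadjusted p under 0.05. Its difference was 4.25 without the second set, with an adjusted p of 0.137. Tshz3 at 0.88 ± 0.32, the costimulatory receptor Cd27 at 1.75 ± 0.65, Skint9 at 1.07 ± 0.44 and Serpina1c at 2.55 ± 1.08 followed upward; Serpina1c had means of 2.63 and 0.075, a difference of 0.50 without the first MiG array and no difference once values under 4 were raised to 4. The cystatin Stfa2 was at -2.78 ± 0.70, Camp at -2.06 ± 0.57, Ankrd22 at -1.92 ± 0.55, lactoferrin (Ltf) at -3.18 ± 0.91 and Csta3 at -2.10 ± 0.64 (adjusted p = 1). Stfa2, Camp, Ltf and Csta3 were at -1.82, -1.35, -1.71 and -1.18 without the third Meis1 array, and Camp at -1.86, -0.18 and -4.16 within the sets. The groups did not overlap for 2257 genes, 11.3%, and 7 genes passed with gene-by-gene and 41 with default weights.

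Neutrophil granule genes fell with MEIS1, all 20 below 0 with a median of -1.28 (adjusted p = 3.85e-23; 0.0718 with an estimated correlation), with Ngp at -3.07 ± 1.13 and Itgb2l at -1.44 ± 0.52 (-0.83 and -0.81 without the third Meis1 array). Adjusted over the list alone 2 members passed, against 0 over all genes, and 9 without the second set, where the median was -1.85. The medians were -0.44, -0.11 and -3.09 within the sets, and -0.40 without the third Meis1 array. Monocyte and macrophage genes fell by 0.89, 19 of 20 below 0, with Itgam at -1.68 and Lyz2 at -1.33 (adjusted p = 0.0847 with an estimated correlation), and by 0.46 without the third Meis1 array, where Itgam was at -0.48 and Lyz2 at -0.65. Dendritic cell and MHC class II genes fell by 0.34, with H2-Eb1 at -0.52 (adjusted p = 0.0718 so estimated), and by 0.18 without the second MiG array. Mast cell genes rose by 0.73 and megakaryocyte genes by 0.65 (adjusted p = 0.555 so estimated). Stem and progenitor genes rose by 0.40, with Hlf at 0.77 (adjusted p = 0.467 so estimated). Without the third Meis1 array these 3 medians were -0.083, 0.067 and 0.13 and none passed, and without the first MiG array each had an adjusted p of 0.0525. HOX and PBX program (0.18), DNA repair (0.25), DNA replication (0.15), p53 target (0.23) and hypoxia genes (0.13) passed as higher and myeloid regulators (-0.25) as lower, with adjusted p from 0.0847 to 0.69 so estimated.

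With AML1-ETO and MEIS1 together, Meis1 rose by 4.20 ± 0.52 from the empty vector (adjusted p = 0.00349; 0.0505 without the second set), the 1 gene that passed, with 644 at an unadjusted p under 0.05. Runx1t1 was 6.20 ± 1.05 higher (adjusted p = 0.123; 0.011 without the second set). Tanc2 at 2.19 ± 0.49, the proteoglycan Gpc4 at 3.03 ± 0.73 and Timp3, an inhibitor of matrix proteases, at 3.17 ± 0.77 followed (adjusted p = 0.432), with Gpc4 at 1.88 and Timp3 at 1.83 without the first AE_Meis1 array. Mrc1 was at -2.65 ± 0.52, and at -2.69, -2.13 and -3.13 within the sets. Camp was at -2.74 ± 0.57, F7 at -2.81 ± 0.60, Ly6g2 at -1.42 ± 0.31 and the activin subunit Inhba at -2.13 ± 0.46. Without the second AE_Meis1 and AE_Meis2 arrays 81 genes passed, and 12 without the second AE_Meis1 array alone. With the set as a block 3 passed (Meis1, Mrc1 and Runx1t1), with gene-by-gene weights 1524 and with default weights 2805. Some 980 genes had groups that did not overlap, 4.92%.

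Neutrophil granule genes fell in AE_Meis1 by a median of 2.11 from the empty vector, with 19 of 20 below 0, Ltf at -4.03 ± 0.91 and Cd177 at -2.56 ± 0.62. Monocyte genes fell by 1.91, with 19 of 20 below 0, Ctss at -2.93 ± 0.73, Ccr2 at -2.20 ± 0.51 and lysozyme (Lyz2) at -2.09 ± 0.55. These 2 were the only list results, of 275, that also passed with an estimated correlation (adjusted p = 0.0339 and 0.0283), and fry, which tests whether a list moved one way on balance, gave 0.0835 and 0.0688 (0.0633 for either direction in both). Adjusted over the list alone 10 and 12 members passed, against 0 over all genes. The medians were -2.25, -1.04 and -2.59 for the granule list and -1.04, -1.86 and -1.97 for the monocyte list within the sets. Myeloid regulators and receptors fell by 1.08, with Csf1r, the M-CSF receptor, at -2.67 ± 0.71, Klf4 at -1.88 ± 0.55 and Irf8 at -1.84 ± 0.60 (adjusted p = 0.153 with an estimated correlation), and 3 members passed adjusted over the list alone. Megakaryocyte genes rose by 1.61, with Treml1 at 2.34 ± 0.73 (1.11 without the first AE_Meis1 array; adjusted p = 0.132 so estimated). Their medians were 4.43, -1.03 and 1.48 within the sets, 0.62 without the first AE_Meis1 array and 2.92 without the second. Stem and progenitor genes rose by 0.55, with Esam at 2.17 and Slamf1 at 2.45 (adjusted p = 0.106 so estimated). Without the first AE_Meis1 array the stem median was 0.31, Esam 0.77 and Slamf1 0.87, and without the second they were 1.21, 3.29 and 4.19. Cholesterol synthesis genes fell by 0.46, with Insig1 at -0.97 and Fdps at -0.71 (adjusted p = 0.407 so estimated), and stood at -0.11 without the second AE_Meis1 array (adjusted p = 0.134). Mast cell (0.79), erythroid (1.02), p53 target (0.092) and cytokine genes (0.12) passed as higher, and dendritic cell (-0.18), mitotic (-0.35), DNA replication (-0.36) and unfolded protein genes (-0.33) as lower, with adjusted p from 0.106 to 0.636 so estimated.

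**Figure D3:**
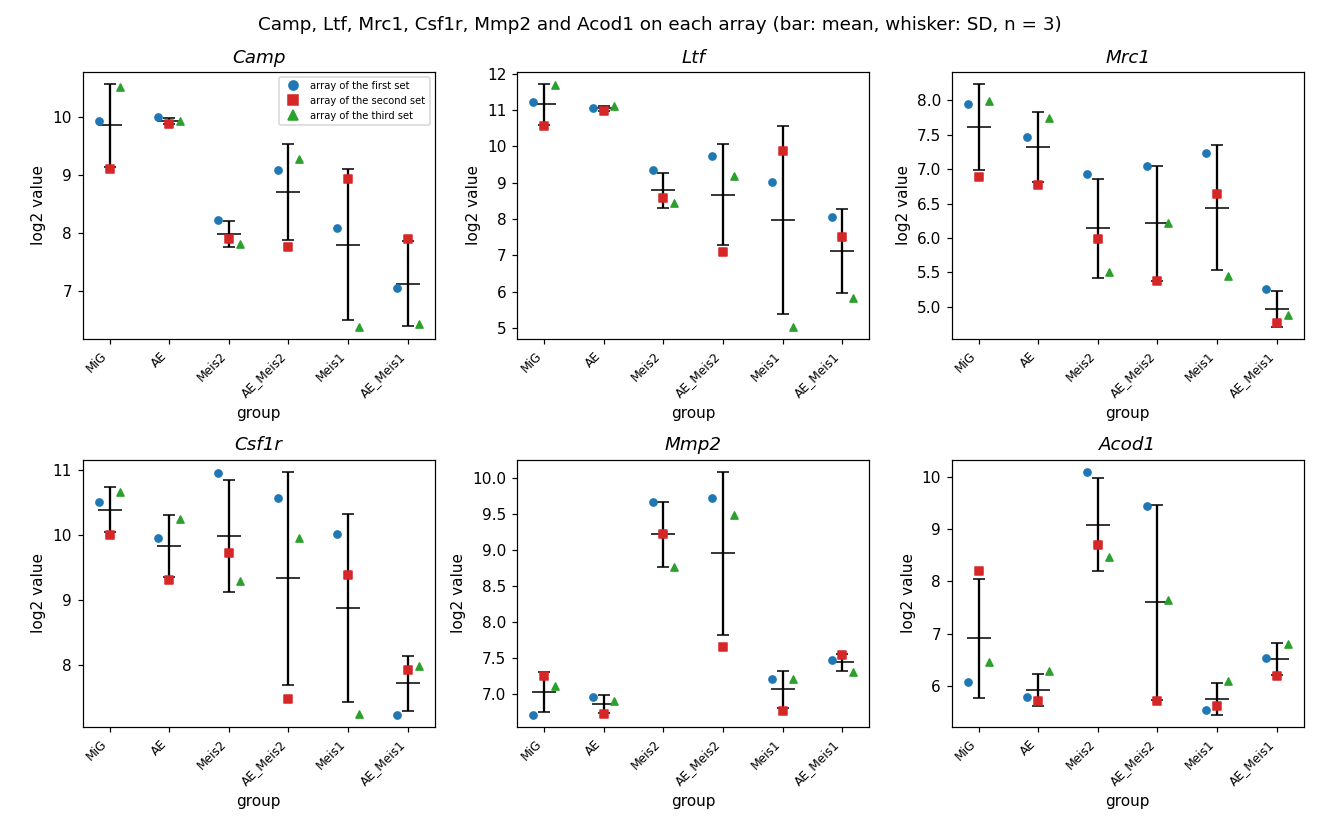
Deposited log2 value of Camp, Ltf, Mrc1, Csf1r, Mmp2 and Acod1 on each array, by group; points are arrays, marked by the set of title codes, bars are means and whiskers SD (n = 3). Mrc1 had its lowest group mean, 4.96, in AE_Meis1, and Mmp2 its highest, 9.22 and 8.96, in Meis2 and AE_Meis2, where the second AE_Meis2 array lay below the other AE_Meis2 arrays.

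Adding MEIS1 to AML1-ETO raised Meis1 by 3.93 ± 0.52 (adjusted p = 0.00912), the 1 gene that passed, with 535 at an unadjusted p under 0.05. Its difference was 3.89 without the second set (adjusted p = 0.139), and 0 genes passed without the first or second AE array or the first or the third AE_Meis1 array. Ly6g2 was at -1.74 ± 0.31 (adjusted p = 0.196), and at -1.65, -1.70 and -1.88 within the sets. It passed with quantile normalization or with the set as a block. Camp was at -2.82 ± 0.57 (adjusted p = 0.628), Itgb2l at -2.40 ± 0.52, Mrc1 at -2.36 ± 0.52 and Stfa2 at -3.05 ± 0.70 (0.952). Gpc4 at 2.51 ± 0.73, Tanc2 at 1.64 ± 0.49, Zfp300 at 1.72 ± 0.53 and the guidance receptor Robo3 at 2.52 ± 0.80 were higher (0.952), and Gpc4, Zfp300 and Robo3 were at 1.37, 1.10 and 1.38 without the first AE_Meis1 array. The groups did not overlap for 851 genes, 4.27%, and 845 genes passed with gene-by-gene and 2 with default weights.

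Neutrophil granule genes fell on adding MEIS1 to AML1-ETO, with a median of -2.18, 18 of 20 below 0, Ltf at -3.91 ± 0.91 and Cd177 at -2.49 ± 0.62 (adjusted p = 1.78e-26; 0.0929 with an estimated correlation). Adjusted over the list alone 13 members passed, against 0 over all genes, and the medians were -2.09, -1.25 and -2.33 within the sets. Monocyte and macrophage genes fell by 1.54, with Itgam at -2.38 and Ccr2 at -1.71 (adjusted p = 0.113 with an estimated correlation), and 6 members passed adjusted over the list alone. Myeloid regulators fell by 0.99, with Csf1r at -2.11 and the granulocytic factor Gfi1 at -1.40 (adjusted p = 0.173 so estimated), and by 1.62 without the third AE_Meis1 array. Megakaryocyte genes rose by 1.21, with Treml1 at 2.24 (1.01 without the first AE_Meis1 array; adjusted p = 0.29 so estimated), at 3.62, -1.20 and 1.23 within the sets, 0.095 without the first AE_Meis1 array (adjusted p = 0.639) and 2.63 without the second. Cholesterol synthesis genes fell by 0.35, with Dhcr7 at -0.86 (adjusted p = 0.437 so estimated), and mitotic genes by 0.40 (adjusted p = 0.528 so estimated); they were at -0.019 and -0.018 without the second AE_Meis1 array. Of the other 11 lists that passed, erythroid (0.65), mast cell (0.34), stem (0.39), stromal (0.28) and cytokine genes (0.22) were higher. DNA replication (-0.42), DNA repair (-0.43), eosinophil (-0.21), unfolded protein (-0.33), hypoxia (-0.32) and reported AML1-ETO target genes (-0.37) were lower, with adjusted p from 0.173 to 0.558 so estimated.

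Compared directly, MEIS2 and MEIS1 differed in Meis1, which fell by 3.91 in Meis2 relative to Meis1 (SE 0.52; adjusted p = 0.00964), the 1 gene that passed, with 42 at an unadjusted p under 0.05. No gene passed without the first or second array of either group or without the third Meis1 array. Meis1 did not pass without the second set (adjusted p = 0.196) or with only the arrays of these 2 groups (0.212). Meis2 was 7.46 ± 1.23 higher (adjusted p = 0.0948), and passed without the second set (0.00698) and with the set as a block (9e-04) and Mmp2 2.16 ± 0.43 (0.632), with 2.46, 2.46 and 1.56 within the sets. Acod1, which makes itaconate in activated macrophages, was 3.34 ± 0.70 higher (adjusted p = 0.766), with 4.56, 3.09 and 2.37 within the sets. Cp was 1.55 ± 0.42 and Tnip3 2.50 ± 0.72 higher. Skint9 was at -1.09 ± 0.44, the cytokine receptor Flt3 at -1.31 ± 0.55, Akr1c18 at -1.89 ± 0.82 (-1.20 without the first Meis2 array) and Rnu6 at -1.19 ± 0.52, the last with no difference once values under 4 were raised to 4 (adjusted p = 1). Some 723 genes had groups that did not overlap, 3.63%.

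Mast cell and basophil genes fell by 0.72 in Meis2 relative to Meis1, with 14 of 15 below 0 (adjusted p = 9.21e-10; 0.227 with an estimated correlation). Neutrophil granule genes rose by 0.38, with 17 of 20 above 0, and Ngp at 1.86 (-0.39 without the third Meis1 array, 2.80 and 3.15 without the first and the second; adjusted p = 0.227 with an estimated correlation). Their medians were -0.080, -0.35 and 1.56 within the sets. Monocyte genes rose by 0.29, with Gpnmb at 2.04 ± 0.70 (adjusted p = 0.319 so estimated), and megakaryocyte genes fell by 0.50 (adjusted p = 0.496 so estimated). Without the third Meis1 array the 4 medians were 0.17, -0.30, -0.082 and 0.060. Without the first Meis2 array the mast cell median was -0.28, the monocyte median 0.028 (adjusted p = 0.887) and the megakaryocyte median -0.29 (0.167), and without the second Meis2 array the megakaryocyte median was -0.19 (0.071) and the mast cell median -0.22. Eosinophil genes fell by 0.25 (adjusted p = 0.101 so estimated), and stood at 0.052 without the second Meis1 array and -0.15 without the first Meis2 array (adjusted p = 0.197). Cytokine and chemokine genes rose by 0.12, with 14 of 21 above 0, Cxcl2 at 1.96 ± 0.61, Il1rn at 1.56 ± 0.57 and Il1b at 1.24 ± 0.54 (adjusted p = 0.223 so estimated), and stood at 0.0059 without the first Meis1 array and -0.039 without the third Meis2 array. Stem (-0.29) and HOX and PBX program genes (-0.013) passed as lower, and dendritic cell (0.17) and hypoxia genes (0.068) as higher, with adjusted p from 0.101 to 0.616 so estimated.

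In cells with AML1-ETO, Meis1 fell by 4.40 in AE_Meis2 relative to AE_Meis1 (SE 0.52; adjusted p = 0.00178), the 1 gene that passed, with 331 at an unadjusted p under 0.05. Meis1 did not pass without the second set (adjusted p = 0.0564) or with only the arrays of these 2 groups (0.0505). Meis2 was 6.20 ± 1.23 higher (adjusted p = 0.843), and passed without the second set (0.0116) and with the set as a block (0.012). The adhesion molecule Vcam1 was 3.83 ± 0.81 and the myeloid receptor Pilra 2.69 ± 0.63 higher, with 5.25, 0.90 and 5.33 and with 3.98, 0.28 and 3.82 within the sets. Rab34 was 1.30 ± 0.37 and Mmp2 1.51 ± 0.43 higher. Mab21l1 was at -3.19 ± 0.80, Tanc2 at -1.64 ± 0.49, Gpc4 at -2.39 ± 0.73 and the semaphorin receptor Plxnb3 at -1.68 ± 0.52 (adjusted p = 1), the last 2 at -1.24 and -1.02 without the first AE_Meis1 array. Without the second AE_Meis1 and AE_Meis2 arrays 5 genes passed: Meis1, Mmp2, Pilra, Vcam1 and BC018473, which was 1.36 higher with all arrays. With gene-by-gene weights 796 passed and with default weights 3081. The groups did not overlap for 216 genes, 1.08%.

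Neutrophil granule genes rose in AE_Meis2 relative to AE_Meis1 by a median of 1.12, with 18 of 20 above 0, Hp at 2.30 ± 0.81, Fcnb at 2.53 ± 0.99 and Camp at 1.59 ± 0.57 (adjusted p = 7.09e-22; 0.0794 with an estimated correlation). Their medians were 2.0, -0.051 and 1.97 within the sets. Megakaryocyte genes fell by 1.93, all 11 below 0, with Treml1 at -1.93, and mast cell genes by 1.69, with Mcpt4 at -3.36 (adjusted p = 0.0794 with an estimated correlation for both). Stem and progenitor genes fell by 0.66, with Esam at -2.00 (adjusted p = 0.0794 so estimated). Monocyte and macrophage genes rose by 0.69, with Itgam at 1.58 (adjusted p = 0.18 so estimated), and myeloid regulators by 0.82 (adjusted p = 0.286 so estimated). Without the first AE_Meis2 array the last 2 lists had an adjusted p of 0.242, with medians of 0.21 and 0.44, and without the second AE_Meis2 array their medians were 1.36 and 1.47. The myeloid regulators were also lost without the second AE_Meis1 array (0.61, adjusted p = 0.163) and the third AE_Meis2 array (0.51, 0.0505), and stood at 0.50 without the first AE_Meis1 array. The monocyte median was 0.45 without the third AE_Meis2 array. Without the first AE_Meis1 array the megakaryocyte and stem medians were -0.70 and -0.26, with Treml1 at -0.70, Esam at -0.59 and Mcpt4 at -2.06. Without the second AE_Meis1 array the medians were -3.08 and -1.34, with Esam at -3.11 and Mcpt4 at -5.25. The mast cell median was -0.95 without the second AE_Meis2 array and -3.10 without the second AE_Meis1 array. Erythroid (-0.98), p53 target (-0.45) and cytokine genes (-0.23) also passed as lower, with adjusted p from 0.0794 to 0.619 so estimated. Adjusted over the list alone no member passed with all arrays, and without the second set 10 megakaryocyte, 4 neutrophil granule and 4 stem members did.

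**Figure D4:**
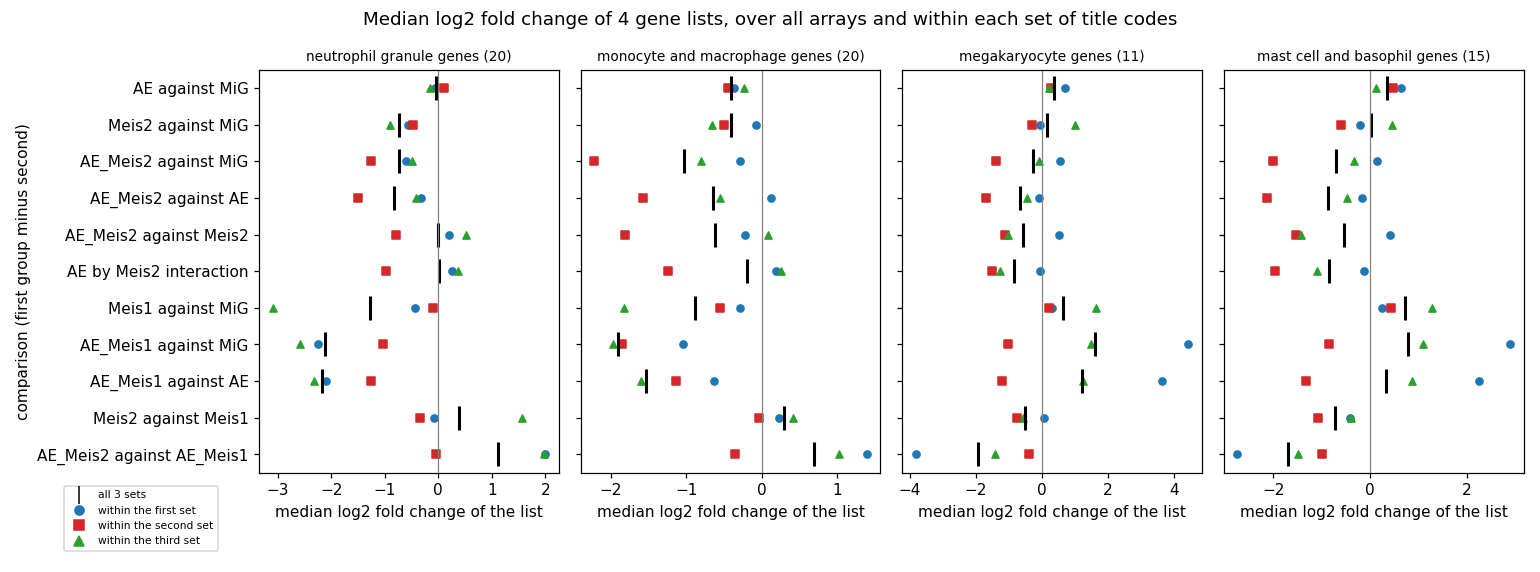
Median log2 fold change of 4 gene lists in each comparison, with the number of measured members in brackets; black bars use all arrays and points are differences within 1 set of title codes, 1 array per group. Neutrophil granule genes were below 0 within each set in Meis2, Meis1, AE_Meis2 and AE_Meis1 against MiG, while second-set points often lay apart from the others.

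Of 275 list results, 117 passed with the preset correlation. T and NK cell genes, interferon response genes and Wnt and plakoglobin genes passed in no comparison, and their smallest adjusted p-values were 0.081 in AE_Meis2 against AE, 0.182 in Meis1 against MiG and 0.227 in AE_Meis1 against AE. Without the second set 68 results passed, 49 of them among the 117 with the same direction and 4 with the opposite one. With all arrays and without the second set 8 and 6 lists passed in Meis2 against MiG, 12 and 10 in Meis1 against MiG, 14 and 9 in AE_Meis1 against MiG, 17 and 11 in AE_Meis1 against AE, 10 and 4 in Meis2 against Meis1 and 9 and 12 in AE_Meis2 against AE_Meis1.

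Across 19934 genes other than those of the constructs, MEIS2 differences with and without AML1-ETO, which share no array, had a Pearson r of -0.211 and a Spearman rho of -0.444, and r was 0.341 without the second set. The AML1-ETO differences with and without MEIS2 had an r of -0.373 and a rho of -0.464, and r was 0.379 without the second set. The MEIS2 difference from MiG and the MEIS1 difference from AE had an r of 0.0537 and a rho of -0.305, and r was 0.512 without the second set. Meis1 and Meis2, both taken against the same MiG arrays, had an r of 0.775 and a covariance of 0.0657, where unchanged groups simulated with shared controls and the spread of all 18 arrays gave an r of 0.501 and a covariance of 0.144. That spread includes deviations shared within title-code sets, which cancel here only where MiG shares them. With the spread of the 9 arrays once set means were removed, r was 0.499 and the covariance 0.0237. The observed covariance lay between the simulated ones, so whether it exceeds what shared controls give depends on the spread assumed. The signs matched for 85.8% of genes, against 66.7% in either simulation. Genes are not independent replicates, and 3 MiG arrays cannot be split into parts of at least 2 each, so part of the r may come from the shared controls. No call was shared, with 1 in Meis1 and 0 in Meis2.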

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

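The counts over other splits of the arrays were planned before the results were seen, and the 9 tests of explanations were chosen after.

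In the interaction, 8 gene lists drew attention because the interaction term itself passed in camera with the preset correlation. Their medians, each for MEIS2 with AML1-ETO minus MEIS2 without it, were -0.84 for mast cell and basophil genes, -0.852 for megakaryocyte genes, -0.43 for mitotic cell cycle genes and -0.443 for DNA replication genes. They were -0.667 for DNA repair genes, -0.412 for cholesterol synthesis genes, -0.357 for unfolded protein and amino acid stress genes and -0.638 for hypoxia and glycolysis genes. None of the 8 passed with an estimated correlation (adjusted p = 0.752). Without the second AE_Meis2 array the mitotic, DNA replication and DNA repair medians were 0.0889, 0.0694 and 0.113 and the unfolded protein median -0.0311, and without the second title-code set the cholesterol median was 0.22. Other splits of the 12 arrays gave as many lists as the real split in 64 of 100, with 8 lists for the real split and up to 13 for another, so chance was not excluded and the medians are not read as a dependence on AML1-ETO. In genes all 100 splits called 0 in limma, which says nothing for or against chance.

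A single probe set drew attention as a signal in data that the comparisons by gene do not use. Probe set 10468877 averaged 15.6 on the 3 MiG arrays (SD 0.343, 15.4 to 16) and lay between 6.45 and 8.58 on the 15 others. It passed in limma in 6 of the 6 comparisons that involve MiG. The gene table does not list it, and no explanation was tested.

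The second title-code set stood apart in every group: 25 genes were at least 2 higher on its 6 arrays than on the other 12, and 1 was at least 2 lower. The median rise was 4.19, from 3.49 to 5.26 by array, led by Mest (8.84), Ebf1 (7.86), Nrn1 (7.73), Gtsf1 (7.43) and Lef1 (6.61). RNA of mouse B cells as the whole source was argued against by the 12 measured B cell genes other than Ebf1 and Pax5. They rose by a median of 0.568 (SD 0.75, Rag2 highest at 2.25), below 7.86 for Ebf1 and 4.19 for Pax5. Cd79a rose by 0.915 while Cd79b was at -0.334. This test holds for mouse RNA only. Weak hybridisation that pulls values to the middle was argued against too, as 80% of the genes had a mean above the upper quartile of those arrays, 9.33. An effect of the delivered constructs was argued against by arrays with the same construct: with each group in turn left out of the choice of genes, its second-set array was higher than its other 2 by a median of 3.43 to 5.36 over 25 to 28 genes (SD 1.68 to 1.98), and by 3.49 in MiG, which carries the vector alone; a preparation batch may be a source, and no record names one.

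Mitotic cell cycle genes were lower in AE_Meis2 than in AE, at a median of -0.361 over 19 members. The first and the third set together gave -0.0153, with 0.00268, -1.14 and -0.0201 within the 3 sets, so hardly any fall was seen outside the second. The SD of 0.0497 is over members, not arrays, so an effect of the added MEIS2 construct stays open. The second AE_Meis2 array, which correlated least with the others, is a candidate explanation: without it the median was 0.117. Donor sex as the cause goes against the within-set values, which rest on 1 array of each group and so leave it open: in the second set, with -1.14, AE and AE_Meis2 both had Xist (10.1 and 9.38) and Kdm5d (8.71 and 7.22), and in the third, with -0.0201, Kdm5d was 4.82 in AE and 7.62 in AE_Meis2.

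Neutrophil granule genes were lower in Meis1 against MiG (median -1.28) and in AE_Meis1 against AE (-2.18) with the preset correlation, but neither passed with an estimated one (adjusted p = 0.0718 and 0.0929), and the first was -0.396 without the third Meis1 array. The second title-code set as the cause was argued against by a median of -1.85 for Meis1 against MiG without it. Donors of both sexes may contribute: in the first set, where all 6 arrays had low Xist and high Kdm5d, the median was -0.441, which goes against it as the whole cause but rests on 1 array of each group and so leaves it open, and in the third set, where MiG had the female and Meis1 the male pattern, it was -3.09. An effect of the MEIS1 construct stays open too: 6 of 6 within-set medians lay below 0 (-0.441, -0.106 and -3.09, and with AML1-ETO -2.09, -1.25 and -2.33). The list was picked from these same arrays, each value is 1 array against 1, and the count adds no independent evidence.

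For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. Only some keep, like the real one, 1 array of each title-code set per side, so the counts measure the sets as well as chance. In genes, 10 of 10 splits gave as many as the real one in AE, Meis2 and AE_Meis2 against MiG and in AE_Meis2 against AE and against Meis2, each with 0 in the real split and 0 as the highest other, which is fixed by a count of 0 and says nothing for or against chance. The real split alone (1 of 10) gave its 1 gene in Meis1 against MiG, AE_Meis1 against MiG and Meis2 against Meis1, where the highest other gave 0. In AE_Meis1 against AE 2 of 10 splits gave 1 gene, the real one and another. In AE_Meis2 against AE_Meis1 5 of 10 did, and another split called 14223 genes against 1, so these 6 arrays differ in ways that do not follow the groups. In lists, with the real count and the highest other, the splits were 8 of 10 in AE against MiG (5, 9), 8 in Meis2 against MiG (8, 13), 5 in AE_Meis2 against MiG (10, 12), 1 in AE_Meis2 against AE (14, 13) and 3 in AE_Meis2 against Meis2 (10, 10). They were 5 in Meis1 against MiG (12, 14), 3 in AE_Meis1 against MiG (14, 15), 1 in AE_Meis1 against AE (17, 14), 7 in Meis2 against Meis1 (10, 15) and 6 in AE_Meis2 against AE_Meis1 (9, 12).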

How the results depend on the processing

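Leaving out the second AE_Meis1 and AE_Meis2 arrays, leaving out the second title-code set, the gene-by-gene array weights and the raising of values under 4 to 4 were chosen after seeing the data; the other alternatives were planned. Except where a reason is given, the cause of a change was not tested. For 297 results on single genes and lists, 3966 alternative values kept direction and side of the threshold, 286 kept direction and newly passed, 168 kept direction and no longer passed, and 113 turned. A list counts as turned where its median or its direction in camera turned. All 232 gene results kept both with the trend and robust prior, and with quantile normalization 231 did and 1 newly passed, while 64 lists kept both and 1 no longer passed. Counts of genes that pass follow. They were 0 with all arrays in AE, Meis2 and AE_Meis2 against MiG, AE_Meis2 against AE and against Meis2 and the interaction, and 1 elsewhere.

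With quantile normalization AE_Meis1 against AE had 2 genes. Testing all probe sets gave 1 in AE, Meis2 and AE_Meis2 against MiG and in the interaction, 2 in Meis1 and AE_Meis1 against MiG, and 0 in AE_Meis1 against AE and in Meis2 against Meis1. In the 6 comparisons that involve MiG, a probe set without a listed gene passed that the tests by gene leave out. Leaving out low-signal genes, which leaves fewer tests, gave 1 in Meis2 against MiG and in AE_Meis2 against AE, and 2 in AE_Meis2 and AE_Meis1 against MiG and in Meis2 against Meis1. There 137 gene results kept direction and side and 6 newly passed; of the lists 51 kept both, 10 no longer passed and 2 turned, the cytokine and chemokine genes, with medians of -0.0455 in Meis2 against MiG and 0.00803 in Meis2 against Meis1. Raising values under 4 to 4 left 230 gene results in place and took 2 to 0, Serpina1c in Meis1 against MiG and Rnu6 in Meis2 against Meis1, since both groups lay under 4. Of those in place, Nlrp4e in AE_Meis2 against Meis2 went from 1.11 to 0.155 and Zfp616 in AE against MiG from -0.867 to -0.374. The arrays carry no measure of background, so a difference between means this low is not read here.

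Fitting only the arrays of the compared groups gave 1 gene in AE against MiG, 5 in Meis2 against MiG, 2 in AE_Meis2 against MiG, 1 in AE_Meis2 against AE and 1 against Meis2, 36 in AE_Meis1 against MiG, 15 in AE_Meis1 against AE and 0 in Meis2 against Meis1. Of the gene results 212 kept direction and side, 18 newly passed and 2 no longer passed, Meis1 in Meis2 against Meis1 (adjusted p = 0.212) and in AE_Meis2 against AE_Meis1 (0.0505).

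The title-code sets were checked as pairs. Deviations from the group means correlated within a set from -0.006 to 0.872 (median 0.632) in the first. They did so from 0.356 to 0.906 (0.728) in the second and from 0.0933 to 0.878 (0.439) in the third. Not every pair was over 0.1, so the main model did not pair arrays by code. Each median was, so the main p-values ignore a pairing that these arrays show and hold shared deviations in their error. Meis2 in Meis2 against MiG had an adjusted p in limma of 0.0892 in that model and 0.000758 with the set as a block. For Runx1t1 in AE against MiG these were 0.256 and 0.00821. With the title-code set as a block, 1 gene passed in AE against MiG, 1 in Meis2 against MiG, 2 in AE_Meis2 against MiG, 2 in AE_Meis2 against AE, 1 in AE_Meis2 against Meis2, 3 in AE_Meis1 against MiG, and 2 in AE_Meis1 against AE, in Meis2 against Meis1 and in AE_Meis2 against AE_Meis1. The block called Meis2 beside Meis1 in the last 2 of these (adjusted p = 9e-04 and 0.012). It made 12 gene results newly pass and left 220 as they were, and of the lists 64 stayed and 1 no longer passed.

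Default array weights gave 8331 to the third AE_Meis2 array and 1.275e-29 to the third AE array, so they compare few arrays. With them 243 genes passed in Meis2 against MiG, 6026 in AE_Meis2 against MiG, 9 in AE_Meis2 against AE, 1976 in AE_Meis2 against Meis2, 41 in Meis1 against MiG, 2805 in AE_Meis1 against MiG, 2 in AE_Meis1 against AE, 10 in Meis2 against Meis1 and 3081 in AE_Meis2 against AE_Meis1. Among gene results 126 kept direction and side, 98 newly passed and 8 turned, all Yes1: 0.211 in Meis2 against MiG, -0.385 in AE_Meis2 against MiG, -0.36 in AE_Meis2 against AE, -0.596 in AE_Meis2 against Meis2, -0.571 in the interaction, -0.558 in AE_Meis1 against MiG, -0.533 in AE_Meis1 against AE and 0.173 in AE_Meis2 against AE_Meis1. Gene-by-gene array weights ran from 0.0257 on the second AE_Meis2 array to 13.4 on the third AE array. They gave 123 genes in AE against MiG, 41 in Meis2 against MiG, 675 in AE_Meis2 against MiG, 259 in AE_Meis2 against AE, 2 in AE_Meis2 against Meis2, 7 in Meis1 against MiG, 1524 in AE_Meis1 against MiG, 845 in AE_Meis1 against AE, 6 in Meis2 against Meis1 and 796 in AE_Meis2 against AE_Meis1. Here 118 gene results kept direction and side, 105 newly passed and 9 turned: Gpnmb in AE against MiG at 0.00913, and Yes1 at 0.291 in Meis2 against MiG, -0.523 in AE_Meis2 against MiG, -0.136 in AE_Meis2 against AE, -0.814 in AE_Meis2 against Meis2, -0.427 in the interaction, -0.568 in AE_Meis1 against MiG, -0.182 in AE_Meis1 against AE and 0.0456 in AE_Meis2 against AE_Meis1.

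Of 275 list results, 117 passed. With an estimated correlation 2 did, which widens the spread of a list whose members vary together, with low-signal genes left out 84, with quantile normalization 112, with the set as a block 117, without the second AE_Meis1 and AE_Meis2 arrays 93 and without the second title-code set 68.

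Leaving out the second AE_Meis1 and AE_Meis2 arrays gave 2 genes in Meis2 against MiG, 3 in AE_Meis2 against MiG, 2 in AE_Meis2 against AE, 81 in AE_Meis1 against MiG, 2 in AE_Meis1 against AE, 2 in Meis2 against Meis1 and 5 in AE_Meis2 against AE_Meis1. Of the gene results 203 kept direction and side, 23 newly passed and 6 turned, all Yes1: -1.63 in AE_Meis2 against MiG, -1.38 in AE_Meis2 against AE, -1.6 in AE_Meis2 against Meis2, -1.34 in the interaction, -1.56 in AE_Meis1 against MiG and -1.3 in AE_Meis1 against AE. Of the lists 40 kept both, 13 no longer passed and 12 turned. Those were mitotic (0.159), unfolded protein (0.0702) and myeloid regulator genes (0.152) in AE_Meis2 against MiG, mitotic (0.117) and DNA replication genes (0.163) in AE_Meis2 against AE, cholesterol (0.0108), mitotic (0.119), DNA replication (0.143) and DNA repair genes (0.206) in AE_Meis2 against Meis2, and DNA replication (0.0694), mitotic (0.0889) and DNA repair genes (0.113) in the interaction. The same 12 medians arose without the second AE_Meis2 array alone.

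Leaving out the second title-code set leaves 2 arrays per group. It gave 1 gene in AE against MiG, 1 in Meis2 against MiG, 5 in AE_Meis2 against MiG, 2 in AE_Meis2 against AE, 1 in AE_Meis2 against Meis2, and 0 in Meis1 against MiG and in AE_Meis1 against AE. Of the gene results 211 kept direction and side, 11 newly passed, 5 no longer passed and 5 turned. Meis1 was the gene that no longer passed, with an adjusted p of 0.137 in Meis1 against MiG, 0.0505 in AE_Meis1 against MiG, 0.139 in AE_Meis1 against AE, 0.196 in Meis2 against Meis1 and 0.0564 in AE_Meis2 against AE_Meis1. In AE_Meis1 against MiG the count stayed at 1 with Runx1t1 in its place, and in the last 2 with Meis2. Those that turned were all Yes1: -0.62 in AE_Meis2 against MiG, -0.152 in AE_Meis2 against AE, -0.442 in AE_Meis2 against Meis2, -0.546 in AE_Meis1 against MiG and -0.0769 in AE_Meis1 against AE. Of the lists 31 kept both, 20 no longer passed and 14 turned. Their medians were -0.00697 for hypoxia genes in AE against MiG, 0.131 for cytokine genes in Meis2 against MiG, 0.00791 for mitotic, -0.0152 for unfolded protein and 0.00152 for myeloid regulator genes in AE_Meis2 against MiG, and -0.0153 for mitotic and 0.0212 for DNA replication genes in AE_Meis2 against AE. In AE_Meis2 against Meis2 they were 0.00288 for unfolded protein, 0.105 for cholesterol, 0.045 for mitotic, 0.0532 for DNA replication and 0.105 for DNA repair genes, in the interaction -0.00124 for mitotic genes, and in Meis2 against Meis1 0.0406 for eosinophil genes. The correlation across genes of the MEIS2 differences with and without AML1-ETO turned to 0.341, that of the AML1-ETO differences with and without MEIS2 to 0.379 (-0.247 with quantile normalization), and that of MEIS2 against MiG with MEIS1 against AE moved to 0.512.

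Leaving out 1 array left 2 in its group, with the spread pooled over all groups. The count ran from 0 to 1 in AE against MiG and Meis2 against MiG, from 0 to 2 in AE_Meis2 against MiG and AE_Meis2 against AE, from 0 to 1 in AE_Meis1 against AE and Meis2 against Meis1, and from 1 to 3 in AE_Meis2 against AE_Meis1. It ran from 1 to 12 in AE_Meis1 against MiG, with 12 without the second AE_Meis1 array and 2 without the second MiG array. The 1 gene in AE and in Meis2 against MiG passed without the second MiG array, the 2 in AE_Meis2 against MiG without the second array of either group, and in AE_Meis2 against AE 1 passed without the second AE array and 2 without the second AE_Meis2 array. The 3 in AE_Meis2 against AE_Meis1 came without the second AE_Meis2 array, with 2 without the second AE_Meis1 array. Meis1 in AE_Meis1 against AE no longer passed without the first or second AE array or the first or the third AE_Meis1 array, and in Meis2 against Meis1 it passed only without the third Meis2 array. In Meis1 against MiG the count was 1 without any of the arrays, and in AE_Meis2 against Meis2 and the interaction 0. Of the gene values 1436 kept direction and side, 12 newly passed, 9 no longer passed and 31 turned, and of the list values 358 kept both, 44 no longer passed and 24 turned. The lists turned without the second AE_Meis2 array in comparisons of AE_Meis2 and without the third Meis1 array in those of Meis1, except that eosinophil genes turned without the second Meis1 array and cytokine genes, whose median was near 0, without several. Their ranges were: in Meis1 against MiG mast cell genes from -0.0828 to 1.23; in AE_Meis2 against MiG mitotic genes from -0.643 to 0.159, unfolded protein genes from -0.467 to 0.0702 and myeloid regulators from -0.746 to 0.152. In Meis2 against MiG cytokine genes ran from -0.129 to 0.147. In Meis2 against Meis1 mast cell genes ran from -1.47 to 0.174, neutrophil granule genes from -0.299 to 0.826, monocyte genes from -0.0821 to 0.641, megakaryocyte genes from -0.906 to 0.0597, eosinophil genes from -0.422 to 0.0519 and cytokine genes from -0.0393 to 0.217. In AE_Meis2 against Meis2 cholesterol genes ran from -0.685 to 0.0108, mitotic genes from -0.682 to 0.119, DNA replication genes from -0.687 to 0.143 and DNA repair genes from -0.957 to 0.206. In the interaction DNA replication genes ran from -0.764 to 0.0694, mitotic genes from -0.697 to 0.0889 and DNA repair genes from -1.13 to 0.113, and in AE_Meis2 against AE mitotic genes from -0.67 to 0.117 and DNA replication genes from -0.599 to 0.163. The genes that turned were Ngp in Meis2 against Meis1 (-0.386 without the third Meis1 array, to 3.15) and Yes1. Yes1 ran from -1.48 to 0.756 in AE against MiG, -1.19 to 0.979 in Meis2 against MiG, -1.63 to 1.04 in AE_Meis2 against MiG, -1.38 to 1.5 in AE_Meis2 against AE and -1.6 to 1.21 in AE_Meis2 against Meis2. It ran from -1.34 to 1.54 in the interaction, -1.56 to 1.15 in AE_Meis1 against MiG, -1.3 to 1.62 in AE_Meis1 against AE and -1.77 to 1.58 in AE_Meis2 against AE_Meis1, and passed in none of these. It kept its direction in Meis1 against MiG (-1.77 to -0.232) and Meis2 against Meis1 (0.0535 to 1.88).

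Over these alternatives, 1 array left out included and all probe sets aside, the adjusted p of Meis1 ran up to 0.137 in Meis1 against MiG (from 2.18e-06), 0.0505 in AE_Meis1 against MiG (from 3.1e-06), 0.139 in AE_Meis1 against AE (from 1.73e-05), 0.212 in Meis2 against Meis1 (from 1.84e-05) and 0.0564 in AE_Meis2 against AE_Meis1 (from 2.69e-07). That of Meis2 ran up to 1 in each of its comparisons, from 3.58e-06 in Meis2 against MiG, 1.22e-09 in AE_Meis2 against MiG, 7.84e-08 in AE_Meis2 against AE, 0.000226 in Meis2 against Meis1 and 5.15e-07 in AE_Meis2 against AE_Meis1. That of Runx1t1 also ran up to 1, from 1.09e-05 in AE against MiG, 5.18e-08 in AE_Meis2 against MiG, 3.27e-08 in AE_Meis2 against Meis2 and 9.65e-05 in AE_Meis1 against MiG.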

Other observations

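Genes that differ between the sexes did not read alike across the arrays, and the labels give no sex. On the 6 arrays of the first title-code set Xist lay between 3.81 and 5.07 and the Y-linked Kdm5d between 10.5 and 10.6. In the second set the Meis1 and Meis2 arrays had Xist at 12.2 and 12 and Kdm5d at 1.1 and 4.4, while the other 4 arrays had both, with Xist from 9.38 to 10.1 and Kdm5d from 7.22 to 8.71. In the third set Xist and Kdm5d were at 4.91 and 10.6 in Meis1 and 5.11 and 10.5 in Meis2. They were at 12.4 and 4.82 in AE, 12.2 and 4 in MiG, 12.3 and 9.29 in AE_Meis1 and 12.3 and 7.62 in AE_Meis2. Uty ran from 4.12 to 10.7 and Eif2s3y from 3.63 to 11.2 over the 18 arrays.

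The first 3 principal components of the 18 arrays held 72.06%, 12.54% and 2.841% of the variance. On the first, second-set arrays ran from -7.38 to 198 and the others from -58.2 to -23.5, so it follows that set. Values below 0 numbered 409 on the second AE_Meis1 array and 403 on the second AE_Meis2 array, and between 61 and 162 on each of the other 16. The highest value of an array was 16 on the second MiG array and at most 15.5 on each of the others.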
